A study of Mus musculus with 933 samples.

How the data were processed

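The study made mouse embryos (strain FVB) by intracytoplasmic sperm injection with sperm of the testis, the caput epididymis or the cauda epididymis, and sequenced RNA of single embryos by Smart-seq2, per the labels. In the injection experiments RNA was injected 3 h after fertilization, per the series design. The deposited data are 12 tables with 933 embryo libraries in 33 groups of 8 to 42 embryos at 5 stages. Each table lists 23845 genes. Per the submitters' processing notes the authors used Bowtie and genome build mm10, and the notes and labels give no versions, no counting tool and no annotation release.

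The values deposited by the authors are TPM in all 12 tables: the values of each library sum to between 999998.77 and 1000000.98. Such values hold no read counts, so the depth of each library is unknown and methods for counts were not used. Precision is therefore given by the spread between embryos. Between 4864 and 12629 genes per library reached 1 TPM, with a median of 10627. No pair of libraries was identical, and the highest correlation of any pair within a table was 0.9879. Of the gene symbols, 27 had been turned into dates and 27 of them were restored from the transcript identifiers beside them. Positions were found for 23806 genes in a RefSeq gene table of the same build, and transcript sequences for 23653 (99.2%). No gene encoded on the mitochondrial genome is listed. Beside the values of blastocyst cohort 4, 2 further columns list 126 library names with a number close to that of the genes at 1 TPM. Of these libraries 3 have no values in the table, and their numbers are the lowest (30, 1034 and 9774, against 10071 or more for the others), so libraries appear to have been left out by the authors.

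Groups were taken from the labels: sperm source, injected RNA, stage and hours after fertilization. A session is the date or number of the day or batch in the sample titles or descriptions. For 8 cauda embryos of blastocyst cohort 3 the title and the description give different sessions, which were merged. Growth and collection notes state 28 h for every sample, although the labels give other stages, and the stage labels were used.

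Each of 21 comparisons was tested with limma 3.58.1 in R 4.3.3: a linear model on log2(TPM + 1) with group and session as fixed effects, moderated t with an intensity trend and robust variances, and Benjamini-Hochberg adjustment. A gene was tested when it reached 1 TPM in at least 50% as many embryos as the smaller group holds, and called at an adjusted p under 0.05. Tables with several groups were fitted over all groups together. Fold changes are back-transformed from the fitted log2 change. They are ratios of geometric means of TPM + 1, adjusted for session, and can lie above or below the ratio of the mean TPM given. The added 1 lowers the fold change of low genes. Embryos, not sessions, were the replicates. TPM are shares of a library, so a change is relative to all listed genes.

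The 4C signature score of an embryo is the mean log2(TPM + 1) of the 100 genes with the highest moderated t in 4-cell cohort 1, caput minus cauda, minus the mean of the 100 with the lowest. These genes were taken among those tested both there and in the comparison being scored, so they can differ between comparisons. The 26 GFP-injected embryos had a mean score of -0.746 in the comparison with cauda and -0.885 in that with EpiM embryos. A Blastocyst signature score was built in the same way from blastocyst cohort 1. Group differences adjusted for session were tested by 100000 permutations of the labels within sessions, adjusted over 28 tests, and 10 differences between such differences were tested by permutation of residuals. Overlaps of called genes are given beside the number that independent lists of those sizes would share. Gene lists (30, of which 29 had members tested) were written before the values were seen and tested with camera of limma at a preset correlation of 0.01, and again with the correlation estimated from the data, adjusted over the lists of a comparison. The genes of a list were also adjusted over the list alone.

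Genes were named by a rule. From the called genes with a mean of at least 5 TPM in the higher group, without symbols of predicted genes or pseudogenes, it takes the 8 with the largest change in each direction in the comparisons set as primary and 4 in the others. It adds up to 4 called members of each list and up to 15 genes per stage called in several cohorts. Where none was called, the 2 genes with the smallest p were named as not passing. The groups, comparisons, tests, score, lists, rule for named genes and the first set of alternatives below were set before the data were examined. The tests of score differences between stages, cohorts and sperm sources (testis against caput) and the splits of the samples were not among them.

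Alternatives set in advance were a pseudocount of 0.1, no filter on low values, no session term, a block for the embryo number, a single mean per session and group, 30 or 300 genes per direction in the score, the other cohort as its source, an adjusted p under 0.1 for overlaps, and the estimated correlation. Added after the data were seen were fits without libraries whose median correlation with their group was below 0.85, and fits after removing, per library, a lowess trend (span 0.3) with the GC share of the first 500 bases of the transcript or with transcript length. Fits that leave out a session at a time, where it held at least 3 embryos of each group, were also chosen after results were seen, and were run for 4-cell cohort 1, morulae and blastocyst cohorts 1 and 4. The tests were tried on simulated data. Of changes added to the values of 4-cell cohort 1 after labels were mixed, 49% of those of 0.5 and 81% of those of 1 on the log2 scale were called, with 5 false calls, and 0 genes were called with no change added. In blastocyst cohort 4 (miRNA against caput) these were 59%, 95%, 3 and 0. Each came from a single mixing of embryos within sessions, which removes any correlation of neighbouring embryos. Another such mixing in blastocyst cohort 4, among the splits below, called 459 genes. The trials therefore do not give the error rate on these data. An added score difference of 0.5 gave median estimates of 0.503, 0.501 and 0.5 in 3 comparisons, and with none added the permutation p was under 0.05 in 5.5%, 5.5% and 4% of 200 runs. These score trials used randomly drawn genes, not the genes of the signature. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for scores and figures.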

Results

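Transcript abundance was measured by single-embryo RNA sequencing in 933 mouse embryos made by intracytoplasmic sperm injection (ICSI), in which a single sperm is injected into an egg. The sperm came from the testis, from the caput (the upstream end of the epididymis) or from the cauda (its downstream end, where sperm are stored). Embryos were harvested at 5 stages: 2-cell embryos at 18, 24 and 28 h after ICSI, then 4-cell, 8-cell, morula and blastocyst embryos. In the injection experiments, RNA was delivered into zygotes of caput sperm 3 h after ICSI. The labels name this RNA as GFP, as EpiM small RNA, as miRNA or as tRF (fragments of transfer RNA). The embryos fall into 33 groups of 8 to 42, spread over 12 tables, and the embryos of a stage within a table are called a cohort here. Values are TPM, a share of all transcripts in a library, which keep no trace of sequencing depth, so the depth of each library is unknown. Between 4864 and 12629 genes per library reached 1 TPM, with a median of 10627. In all, 21 comparisons of 2 groups were made with limma on log2(TPM + 1), with the experimental session as a covariate. Fold changes are back-transformed from the fitted change on that scale, so they can differ from the ratio of the mean TPM given. The added 1 lowers the fold change of low genes. Gene positions are on mouse genome build mm10.

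The 2-cell embryos show whether caput and cauda sperm gave different transcript levels soon after fertilization. Hexim2, an inhibitor of the elongation kinase P-TEFb (chromosome 11, 103123260 to 103139908), was higher with caput sperm at 18 h, at 36.2 ± 9.31 TPM (SD, n = 19) against 22.7 ± 6.54 TPM (SD, n = 25). Its change was 0.69 ± 0.13 on the log2 scale (SE, adjusted p = 0.0253), it was higher in 3 of 3 sessions, and 18 of 19 caput embryos lay above the cauda median. It was the sole gene of 12899 to pass at 18 h, where 724 genes had an unadjusted p under 0.05. The list of genes of the 2-cell transcription burst, such as the Zscan4 and Usp17l families, had a median change of -0.45 at 18 h, with 2 of 20 measured members higher and none passing on its own. The list's adjusted p was 1.9e-09 with a preset correlation between genes, and adjusted p = 0.352 with an estimated correlation. At 28 h, none of 13179 genes passed in limma, with 1031 at an unadjusted p under 0.05. The smallest p values there belonged to Vcl (vinculin) at 24.7 ± 7.95 against 14.5 ± 5.62 TPM and the kinase gene Map3k4 at 16.4 ± 6.47 against 9.21 ± 3.13 TPM (SD, n = 25 and 24, both adjusted p = 0.216). At 24 h, none of 13400 genes passed in limma and 554 had an unadjusted p under 0.05. The smallest p values there belonged to Angptl4, at 0.266 ± 0.883 TPM with caput (SD, n = 11) and 4.25 ± 3.24 TPM with cauda sperm (SD, n = 8), and to Isoc2a, listed at 0 in all 11 caput embryos and at 3.94 ± 4.37 TPM with cauda sperm, both with adjusted p = 1. The Hexim2 call ended without the session term, with the embryo number as a block and with a single mean per session and group.

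At the 4-cell stage, many transcripts were higher with caput sperm and few were lower. In cohort 1, with 32 embryos per group in 4 sessions, 114 genes were higher and 16 lower of 11597 tested. In cohort 2, with 23 embryos per group, 64 were higher and 2 lower of 11511. The cohorts share no libraries, and 53 of the genes called higher were shared between them, where 0.649 would be shared by chance for independent lists. None of the lower genes was shared. The kinase gene Dapk3 (chromosome 10, 81182987 to 81193197) had the largest change in cohort 1, at 69.8 ± 36.9 against 14.9 ± 11.8 TPM (SD), a 5.53-fold difference with a log2 change of 2.47 ± 0.24 (SE, adjusted p = 6.1e-12). In cohort 2 it was at 69.2 ± 39.4 against 20.8 ± 22.1 TPM (SD, adjusted p = 0.000246), with 22 of 23 caput embryos above the cauda median. C2cd4b, on chromosome 9 at 67716224 to 67760933, changed by 2.32 ± 0.33 and 2.10 ± 0.48 in the respective cohorts. The transcription factor gene Cebpb (chromosome 2, 167688915 to 167690432) was at 7.78 ± 10.8 against 0.556 ± 1.4 TPM in cohort 1 and at 3.86 ± 4.91 against 0.447 ± 0.953 TPM in cohort 2. Sox21, another transcription factor gene, was at 26.4 ± 15.4 against 9.91 ± 9.77 TPM in cohort 1, and Yrdc, needed for a modified base of transfer RNA, at 268.9 ± 80.7 against 127.1 ± 91.6 TPM. Klf2, a transcription factor gene of the pluripotency list, was at 223.7 ± 93.7 against 110.4 ± 55.5 TPM in cohort 1 (2.02-fold).

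The 4-cell calls included some genes for RNA-binding and RNA-processing proteins. Of 25 measured genes for heterogeneous nuclear ribonucleoproteins, 5 were higher in cohort 1 and 3 in cohort 2, with none lower. Hnrnpab (chromosome 11, 51600100 to 51606881) was at 732.7 ± 291.8 against 320.4 ± 168.0 TPM in cohort 1 and at 609.1 ± 224.5 against 277.6 ± 174.3 TPM in cohort 2, with adjusted p of 6.1e-12 and 2.51e-06. Hnrnpu was 2.13-fold and 2.02-fold higher and Pcbp1 2.00-fold and 2.02-fold higher in cohorts 1 and 2. The other members went both ways: the list's median change was -0.03 in cohort 1, with 11 of 25 members higher, while its mean t was 1.11. Its adjusted p in cohort 1 was 0.00927 with a preset correlation, and adjusted p = 0.623 with an estimated correlation. The splicing factor genes Srsf1 and Srsf2 were higher in both cohorts, Srsf2 by 1.84-fold and 2.24-fold, as 2 of 36 measured splicing factor genes. Eif3b, for a subunit of the translation initiation factor eIF3 (chromosome 5, 140419305 to 140443358), was at 230.4 ± 82.4 against 100.1 ± 64.2 TPM in cohort 1 and at 250.8 ± 95.4 against 113.3 ± 79.9 TPM in cohort 2. In cohort 1, Smarcd2 (1.81-fold) and Smarcc1 (1.46-fold) were higher as 2 of 24 measured genes of the SWI/SNF remodelling complex, Trim28 (1.40-fold) as 1 of 21 of the DNA methylation list and Ezh2 (1.26-fold) as 1 of 23 Polycomb genes, with estimated-correlation adjusted p = 0.965, 0.766 and 0.965 for these lists. Among the 16 lower genes of cohort 1, Trp53i13 was at 7.33 ± 5.87 against 14.2 ± 6.27 TPM and Xrcc6, for the Ku70 DNA repair protein, at 24.0 ± 12.9 against 35.0 ± 12.4 TPM. The lower genes of cohort 2 were Arl6ip1 (1.40-fold) and Chm (2.21-fold). The genes called higher had a median GC share of 67.2% in the first 500 bases of the transcript in cohort 1 and 68.1% in cohort 2, against 57.6% for all tested genes. It was 68.6% for the genes called higher in morulae and 61.4%, 66.6%, 59.8% and 66.9% in blastocyst cohorts 1 to 4. For the genes called lower with EpiM small RNA it was 67.6%. For those lower with miRNA than in caput embryos it was 66.2% (4-cell) and 67.2% (blastocyst), and against tRF 68% and 68.2%. All tested genes had 57.6% to 57.8% in these comparisons. With a single mean per session and group, 20 genes passed in cohort 1 and 0 in cohort 2 (limma, 737 at an unadjusted p under 0.05), while the 114 higher genes of cohort 1 kept a median change of 0.763, as sessions of equal group sizes require. In cohort 1, 68 genes passed without session day422 and 61 without session day506.

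To follow this difference across embryos that did not define it, a 4C signature score was computed per embryo: the mean log2(TPM + 1) of the 100 genes with the highest moderated t in 4-cell cohort 1, minus that of the 100 with the lowest. The genes were taken among those tested in both comparisons, so they can differ from comparison to comparison. In 4-cell cohort 2 the score was higher with caput sperm by 0.84 ± 0.107 (SE, n = 23 and 23), in 4 of 4 sessions, and 23 of 23 caput embryos lay above the cauda median. A permutation of labels within sessions gave an adjusted p of 4.7e-05, from the smallest p that 100000 permutations can give, 1e-05. In 2-cell embryos the score differed by -0.098 ± 0.1 at 18 h (n = 19 and 25), by 0.114 ± 0.165 at 24 h and by 0.0 ± 0.095 at 28 h (n = 25 and 24), with adjusted permutation p values of 0.51, 0.63 and 1. The difference at the 4-cell stage exceeded that at 28 h by 0.84 ± 0.143 (adjusted permutation p = 3.3e-05). The genes were chosen at the 4-cell stage, which favours a larger difference there. Some of them, such as Klf2, were low at 28 h, while others, such as Hnrnpab, were not. The contrast therefore cannot show when the difference arises.

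**Figure D1:**
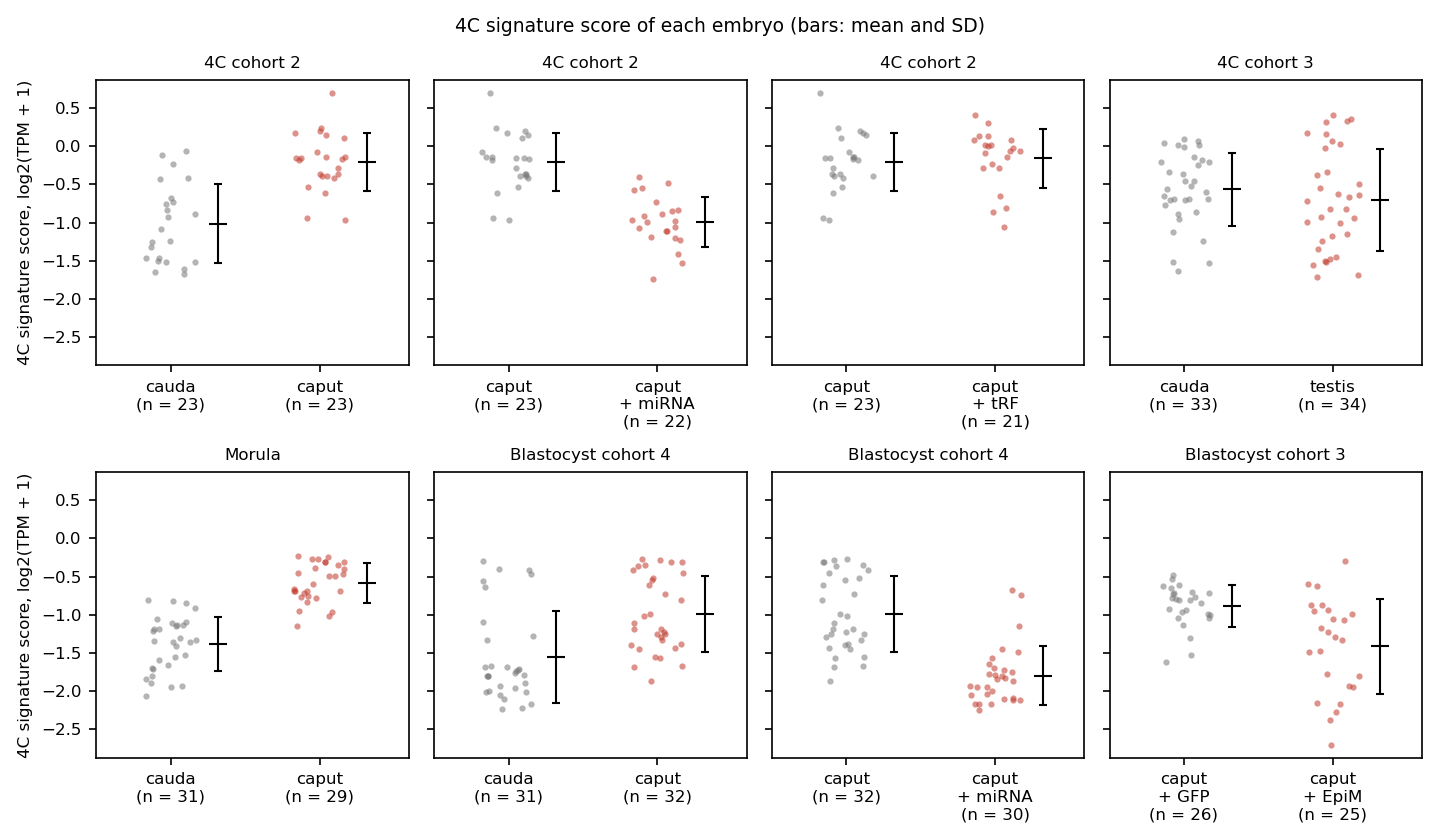
4C signature score of each embryo on the log2(TPM + 1) scale, in 8 comparisons of 2 groups; points are embryos and bars give the mean and SD. In 4-cell cohort 2, 23 of 23 caput embryos lie above the cauda median and 0 of 22 miRNA-injected embryos above the median of caput embryos.

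In 8-cell embryos no gene of 11774 passed in limma, with 541 at an unadjusted p under 0.05. Eif3b was among the 2 genes with the smallest p, at 218.1 ± 90.6 TPM with caput (SD, n = 28) and 118.3 ± 59.96 TPM with cauda sperm (SD, n = 25), with 25 of 28 caput embryos above the cauda median, but its adjusted p was 0.469. The other, Cabp7, was at 3.26 ± 4.94 against 0.835 ± 2.1 TPM with the same adjusted p. Of the 53 genes called higher in both 4-cell cohorts, 51 were measured here and 51 had a higher value with caput sperm, with a median change of 0.56. Caput embryos had a 4C signature score higher by 0.415 ± 0.152 (adjusted permutation p = 0.024, higher in 3 of 3 sessions that held both groups). Only 3 of the 6 sessions held both groups, with 3, 4 and 4 caput embryos and 3, 17 and 5 cauda embryos. The other caput embryos come from sessions without cauda embryos. They enter the means and the 25 of 28 above, but they do not inform the differences adjusted for session. With 300 genes per direction the score difference was 0.199 with an adjusted permutation p of 0.55.

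In morulae, 91 genes were higher with caput sperm and 8 lower of 11519, among 29 caput and 31 cauda embryos. Of the genes called higher in 4-cell cohort 1, 63 were also called higher in morulae, against 0.963 by chance for independent lists. The labels give sessions day422, day423, day426 and day506 for 4-cell cohort 1 and day423, day424, day427 and day507 for morulae. With day423 in both, the embryos may share males or clutches, which the labels do not give. Pcbp1 (chromosome 6, 86524480 to 86526189) had the smallest p, at 762.2 ± 308.1 against 254.7 ± 68.1 TPM (SD, 2.80-fold, adjusted p = 1.39e-13), with 29 of 29 caput embryos above the cauda median. Cebpb was at 5.90 ± 6.26 against 0.387 ± 1.95 TPM, Eif3b at 195.9 ± 71.5 against 66.7 ± 38 TPM and Dapk3 at 42.7 ± 24.2 against 17.2 ± 25.4 TPM. Fancf, for a protein of the Fanconi anaemia repair complex, was 3.48-fold higher. Hnrnpu and Hnrnpab were 2.54-fold and 2.36-fold higher, and Hdac2, for a histone deacetylase, 1.64-fold. Gata6, a transcription factor gene of the primitive endoderm, was at 110.1 ± 36.1 against 73.9 ± 22.5 TPM (adjusted p = 0.00191), and Gata3, a transcription factor gene of the trophectoderm, was lower with caput sperm, at 31.8 ± 29.2 against 52.4 ± 31.3 TPM (adjusted p = 0.0158). Of 27 trophectoderm genes measured, 7 had a higher value with caput sperm and Gata3 alone was called over all genes (2 were lower adjusted over the list alone), with a list adjusted p of 0.0128 at a preset correlation and adjusted p = 0.59 with an estimated correlation. Of 84 ribosomal protein genes, 77 had a higher value with caput sperm, with a median change of 0.11. None was called over all genes and 11 were adjusted over the list alone, and the list's adjusted p was 8.15e-25 with a preset correlation and adjusted p = 0.153 with an estimated correlation. With caput sperm the 4C signature score was higher by 0.794 ± 0.075 (adjusted permutation p = 4.7e-05, 4 of 4 sessions), and 29 of 29 caput embryos lay above the cauda median. With a single mean per session and group, 39 genes passed, without session day423 44 and without session day427 48.

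In blastocysts, caput and cauda sperm were compared in 4 cohorts that share no libraries, and the genes called differed between them. In cohort 1 (35 caput and 42 cauda embryos), 170 genes were higher and 89 lower of 12200. In cohort 2 (34 and 39), 34 were higher and 0 lower of 12154, where 1819 genes had an unadjusted p under 0.05 in limma. In cohort 3, where the caput embryos had been injected with GFP (26 and 39), 49 were higher and 4 lower of 11648 (65 and 17 with the GC trend removed, 62 and 27 with the length trend removed). In cohort 4 (32 and 31), 218 were higher and 4 lower of 12098 (92 and 5 with the GC trend removed, 123 and 6 with the length trend removed). In cohort 1, 1 gene passed without session day512, 13 without day3315, 111 without day317, 171 without day210 and 484 without day120. In cohort 4, 30 passed without session day605, 57 without day606, 242 without day523 and 306 without day529. Cohorts 1 and 2 shared 0 of the genes called higher (0.471 by chance), cohorts 1 and 4 shared 14 (3.03 by chance), cohorts 3 and 4 shared 7 (0.937 by chance) and cohorts 2 and 4 shared 4 (0.632 by chance). Cohort 3 shared 1 with cohort 1 (0.681 by chance) and 1 with cohort 2 (0.146 by chance). Cebpb was called higher in cohorts 2, 3 and 4, at 5.40 ± 4.31 against 1.73 ± 3.65 TPM in cohort 2, at 6.02 ± 5.74 against 1.58 ± 2.78 TPM in cohort 3 and at 4.80 ± 9.59 against 1.87 ± 4.45 TPM in cohort 4. Ybx1, for an RNA-binding protein (chromosome 4, 119277327 to 119296265), was called in cohorts 1 and 4 (1.52-fold and 2.44-fold), Pcbp1 in cohorts 3 and 4 (2.07-fold and 1.75-fold) and Eif3b in cohorts 2 and 4 (1.67-fold and 1.76-fold). Klf5, a transcription factor gene of the pluripotency list, was at 417.2 ± 174.9 against 263.4 ± 201.9 TPM in cohort 4 and at 241.6 ± 147.3 against 152.8 ± 32.8 TPM in cohort 1.

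Blastocyst cohort 4 held 48 of the genes called higher in 4-cell cohort 1, against 2.19 by chance for independent lists. The other blastocyst cohorts held fewer such calls. Of the 53 genes called higher in both 4-cell cohorts, 6, 7, 7 and 28 were called higher in blastocyst cohorts 1 to 4 (50, 51, 51 and 51 measured). Of 25 genes for heterogeneous nuclear ribonucleoproteins, 25 had a higher value with caput sperm, 6 were called over all genes and 18 adjusted over the list alone. The list's adjusted p was 9.3e-13 with a preset correlation and adjusted p = 0.0421 with an estimated correlation. Hnrnpll was 2.27-fold, Hnrnpab 1.89-fold and Hnrnpu 1.83-fold higher, and the RNA-binding protein gene Grsf1 was at 85.4 ± 27.2 against 37.8 ± 30.4 TPM (SD, adjusted p = 1.08e-05), with 32 of 32 caput embryos above the cauda median. Among splicing factor genes, 3 of 36 were called and 33 had a higher value, with a list adjusted p of 1.84e-06 at a preset correlation and adjusted p = 0.422 with an estimated correlation. Of 22 primitive endoderm genes, 20 had a higher value with caput sperm and none was called over all genes (4 adjusted over the list alone), with a median change of 0.44, a list adjusted p of 0.00265 at a preset correlation and adjusted p = 0.555 with an estimated correlation. The lower genes of cohort 4 were Prr15l, Selenbp1, H2-DMb1 and Pde6a, the last 3 falling outside the rule for named genes and chosen after their values were seen. The 4C signature score was higher with caput sperm in all 4 blastocyst cohorts, by 0.34 ± 0.09, 0.303 ± 0.116, 0.495 ± 0.108 and 0.491 ± 0.102 in cohorts 1 to 4, with adjusted permutation p values of 0.001, 0.024, 0.00024 and 0.00016. It was higher in 6 of 6, 4 of 6, 4 of 5 and 6 of 6 sessions. In cohort 3 the labels give an injection for the caput embryos alone, so sperm source and injection cannot be separated there. With a single mean per session and group, 0 genes passed in limma in each of the 4 blastocyst cohorts (1080, 903, 1515 and 948 at an unadjusted p under 0.05), and with 300 genes per direction the score difference was 0.066 in cohort 2 and 0.206 in cohort 4, with adjusted permutation p values of 0.75 and 0.051.

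Blastocyst cohorts 1, 2 and 3 held further calls, and whether these differ between cohorts was not tested. In cohort 1, Sox17, a transcription factor gene of the primitive endoderm, was at 6.09 ± 13.6 against 14.7 ± 18.8 TPM (adjusted p = 0.0462) and the tubulin gene Tuba3a at 9.92 ± 11.5 against 20.8 ± 16.3 TPM. Fgfr3, for a fibroblast growth factor receptor, was higher with caput sperm in cohort 1, at 13.5 ± 13.5 against 5.06 ± 3.42 TPM (2.33-fold), as were the imprinted genes Impact (2.11-fold) and Igf2r (1.6-fold). Of 79 nuclear genes for oxidative phosphorylation, 9 had a higher value with caput sperm in cohort 1 and 2 were called lower (15 adjusted over the list alone), with a list adjusted p of 1.66e-11 at a preset correlation and adjusted p = 0.617 with an estimated correlation. Targets of p53 were called higher in cohort 1 (Trp53inp1, Eda2r and Bbc3, as 3 of 22 measured) and in cohort 3 (Phlda3, Btg2 and Cdkn1a, as 3 of 22), with estimated-correlation adjusted p = 0.617 and 0.571 for the list. Cdkn1a, for a cell cycle inhibitor, was at 185.0 ± 137.7 TPM in GFP-injected caput embryos and 85.0 ± 54.1 TPM with cauda sperm. In cohort 3, 5 of 38 proteasome genes were higher, among them Psmb4 (1.36-fold), with estimated-correlation adjusted p = 0.571 for the list. The sterol genes Sqle and Insig1 were lower in the GFP-injected caput embryos of cohort 3 (2.63-fold and 2.09-fold), as was the stress gene Chac1, and 3 of 23 genes of cholesterol synthesis had a higher value, with estimated-correlation adjusted p = 0.72 for the list. These lower calls ended without the filter on low values (32 genes higher, 0 lower) and without the session term (22 higher, 0 lower). In cohort 2 the largest changes were those of Crls1, for cardiolipin synthase, at 24.5 ± 17.8 against 9.97 ± 9.14 TPM (2.86-fold), and of Cebpb. The genes called in cohort 1 had median transcript lengths of 4752 bases (higher) and 1664 bases (lower), against 2814 for all tested genes. The genes called higher in cohort 2 had a median of 3436.5 bases, against 2799 for all tested genes. In cohort 3 the medians were 1333 bases (higher) and 2727.5 bases (lower), against 2732. Without the session term, 17 genes passed in cohort 1, and 79 in cohort 2. With the embryo number as a block, 0 passed in cohort 1 (limma, 1556 at an unadjusted p under 0.05) and 306 in cohort 2. In cohort 2, 2 genes passed with the GC trend removed and 2 with the length trend removed, with Crls1 called in both of these fits and Cebpb in neither. A Blastocyst signature score built from cohort 1 in the same way did not pass in any of the 8 comparisons of the other blastocyst cohorts, where the smallest adjusted permutation p was 0.12, for cohort 2 (0.238 ± 0.124). Without the session term that difference was 0.321 with an adjusted permutation p of 0.0076.

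Injection of EpiM small RNA into zygotes of caput sperm was compared with injection of GFP in blastocyst cohort 3, with 25 and 26 embryos, which addresses whether small RNA added after fertilization changes these transcripts. Of 11384 genes, 53 were lower with EpiM small RNA and 0 higher, with 542 at an unadjusted p under 0.05 in limma. Hdgf, for a growth factor (chromosome 3, 87906090 to 87916132), had the smallest p, at 119.8 ± 67.8 against 335.0 ± 204.8 TPM (SD, 3.13-fold lower, adjusted p = 4.07e-05), lower in 4 of 4 sessions. Cebpb was at 0.673 ± 1.65 against 6.02 ± 5.74 TPM, Dapk3 at 24.5 ± 26.0 against 71.2 ± 40.2 TPM and Chpt1, for an enzyme of phosphatidylcholine synthesis, at 10.6 ± 8.6 against 33.5 ± 19.6 TPM. Pcbp1 was 3.03-fold, Hnrnpab 2.57-fold and Hnrnpl 1.75-fold lower, as 3 of 25 measured genes for heterogeneous nuclear ribonucleoproteins, a list whose median change was 0.01 and whose adjusted p was 0.203 at a preset correlation. Eif3b and Gata6 were lower by 2.30-fold and 1.93-fold. Of the genes called higher with caput sperm in 4-cell cohort 1, whose libraries are separate, 27 were lower with EpiM small RNA, against 0.558 by chance for independent lists. With EpiM small RNA the 4C signature score was lower by -0.451 ± 0.118 (adjusted permutation p = 0.0015), lower in 4 of 4 sessions, with 3 of 25 embryos above the median of the GFP group. The GFP embryos are also the caput side of the comparison with cauda sperm, so high values in them alone would give both differences. With a single mean per session and group, 0 genes passed in limma (347 at an unadjusted p under 0.05), and with 300 genes per direction the score difference was -0.089 (adjusted permutation p = 0.75).

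Injection of miRNA into zygotes of caput sperm was compared with caput embryos at the 4-cell stage (cohort 2, 22 and 23 embryos). The group label of the caput embryos names no injected RNA. If they were not injected, miRNA and the injection itself cannot be separated in this comparison. Of 11673 genes, 126 were lower and 21 higher. With the GC trend removed these were 93 and 44, and with the length trend removed 107 and 60. Dapk3 was at 10.9 ± 12.8 against 69.2 ± 39.4 TPM (SD, 10.4-fold lower, adjusted p = 1.06e-07), and 22 of 22 injected embryos lay below the caput median. Ino80b, for a subunit of a chromatin remodeller (chromosome 6, 83121765 to 83125119), was at 5.90 ± 7.55 against 20.5 ± 9.51 TPM, and Yrdc at 92.9 ± 82.0 against 263.3 ± 74.8 TPM. Hnrnpab, Hnrnpu and Pcbp1 were 2.52-fold, 2.21-fold and 2.16-fold lower, as part of 5 of 25 called in that list, whose median change was -0.03 and whose adjusted p was 0.168 at a preset correlation. Srsf2, Eif3b, Smarcd2 and Klf2 were lower by 2.64-fold, 2.74-fold, 2.13-fold and 2.09-fold. Gata6 was at 19.9 ± 15.6 against 40.6 ± 19.6 TPM, the imprinted gene Gnas at 29.1 ± 17.7 against 66.1 ± 33.0 TPM, and Ago2, for the Argonaute protein that binds miRNA, at 32.5 ± 10.5 against 47.7 ± 10.5 TPM (adjusted p = 0.00751). Serinc3 (1.65-fold) and Zfp229 (1.92-fold) were among the higher genes. Of the genes called higher with caput sperm in cohort 1, whose libraries are separate, 65 were lower after miRNA injection, against 1.26 by chance for independent lists. The 4C signature score was lower by -0.831 ± 0.097 (adjusted permutation p = 4.7e-05), lower in 4 of 4 sessions, with 0 of 22 embryos above the caput median. The comparison with cauda sperm uses the same caput embryos, so high values in them alone would give both differences.

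After injection of tRF, 1 gene of 11608 was called at the 4-cell stage (21 and 23 embryos): Tceb1, for elongin C, was at 1990 ± 206 against 1635 ± 266 TPM (SD, 1.25-fold higher, adjusted p = 0.00299), with 1014 genes at an unadjusted p under 0.05. That call ended with the embryo number as a block and with a single mean per session and group (0 genes in limma, 952 and 624 at an unadjusted p under 0.05), and with the GC trend removed, where 2 other genes passed. The 4C signature score differed from that of caput embryos by 0.086 ± 0.115 (adjusted permutation p = 0.62). Set directly against tRF, miRNA gave 87 lower and 7 higher genes of 11436, with Dapk3 at 10.9 ± 12.8 against 64.8 ± 38.2 TPM, Hnrnpab 2.60-fold lower and the score lower by -0.862 ± 0.118 (adjusted permutation p = 4.7e-05, 3 of 3 sessions). In that contrast 5 of 25 genes for heterogeneous nuclear ribonucleoproteins had a higher value with miRNA, 4 were called lower, and the list's adjusted p was 4.14e-07 at a preset correlation and adjusted p = 0.000807 with an estimated correlation. Of 21 pluripotency genes, 4 had a higher value with miRNA and Klf2 was called 2.42-fold lower, with a list adjusted p of 0.000423 at a preset correlation and adjusted p = 0.0251 with an estimated correlation. Casp2, for a caspase, was higher with miRNA than with tRF, at 13.3 ± 9.56 against 4.99 ± 5.19 TPM. With a single mean per session and group, 0 genes passed in limma for miRNA against caput embryos (560 at an unadjusted p under 0.05) and 7 for miRNA against tRF.

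In blastocysts (cohort 4), 366 genes were lower and 4 higher of 12113 in 30 miRNA-injected embryos than in 32 caput embryos. The group label of these caput embryos names no injected RNA either, so the same limit holds. With the GC trend removed, 206 were lower and 20 higher, and with the length trend removed 267 and 21. Pcbp1 was at 93.5 ± 43.4 against 283.7 ± 197.1 TPM (SD, 2.92-fold lower, adjusted p = 5.93e-09), with 29 of 30 injected embryos below the caput median. Zmynd19 was at 2.56 ± 2.1 against 15.5 ± 8.04 TPM (4.71-fold), Srsf2 at 68.0 ± 64.4 against 173.6 ± 75.1 TPM (3.26-fold) and Yrdc at 17.4 ± 23.7 against 52.9 ± 29.2 TPM (4.36-fold). Of 25 genes for heterogeneous nuclear ribonucleoproteins, 1 had a higher value after miRNA and 6 were called lower, with a list adjusted p of 1.61e-09 at a preset correlation and adjusted p = 0.159 with an estimated correlation. Of 27 Polycomb genes, 4 were lower, among them Ezh2 (1.51-fold), Eed (1.53-fold) and Yaf2 (2.00-fold), and of 23 genes of the SWI/SNF complex 3 were called lower and 0 had a higher value, with adjusted p = 0.715 with an estimated correlation for each of these lists. Klf5 was 1.76-fold, Gata6 1.6-fold and Ago2 1.55-fold lower. The higher genes were Sdc4 (1.19-fold), Prlr, Myom2 and Gm6083, the last 3 chosen after their values were seen. Of the genes called higher in 4-cell cohort 1, 81 were lower after miRNA here, against 3.63 by chance for independent lists. The score was lower by -0.828 ± 0.104 (adjusted permutation p = 4.7e-05, 6 of 6 sessions). These caput embryos are also those compared with cauda sperm, so high values in them alone would give both differences. For tRF against caput embryos, 0 of 12106 genes passed in limma, with 723 at an unadjusted p under 0.05. Of the 53 genes called higher in both 4-cell cohorts, 51 were measured here. With tRF 45 of them had a lower and 6 a higher value than in caput embryos, with a median change of -0.24. Alg2, for a glycosyltransferase, had the smallest p there, at 13.3 ± 6.02 against 18.5 ± 4.89 TPM (adjusted p = 0.392), and the score differed by -0.121 ± 0.102 (adjusted permutation p = 0.42). Set against tRF, miRNA gave 176 lower genes and 1 higher (Alg2, 1.41-fold) of 11968, with Grsf1 at 28.7 ± 29.7 against 71.0 ± 30.5 TPM and the score lower by -0.652 ± 0.102 (adjusted permutation p = 4.7e-05, 6 of 6 sessions). Without the session term 87 genes passed there, and with the embryo number as a block 89. With a single mean per session and group, 0 genes passed in limma in either miRNA comparison (775 against caput embryos and 421 against tRF at an unadjusted p under 0.05).

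**Figure D2:**
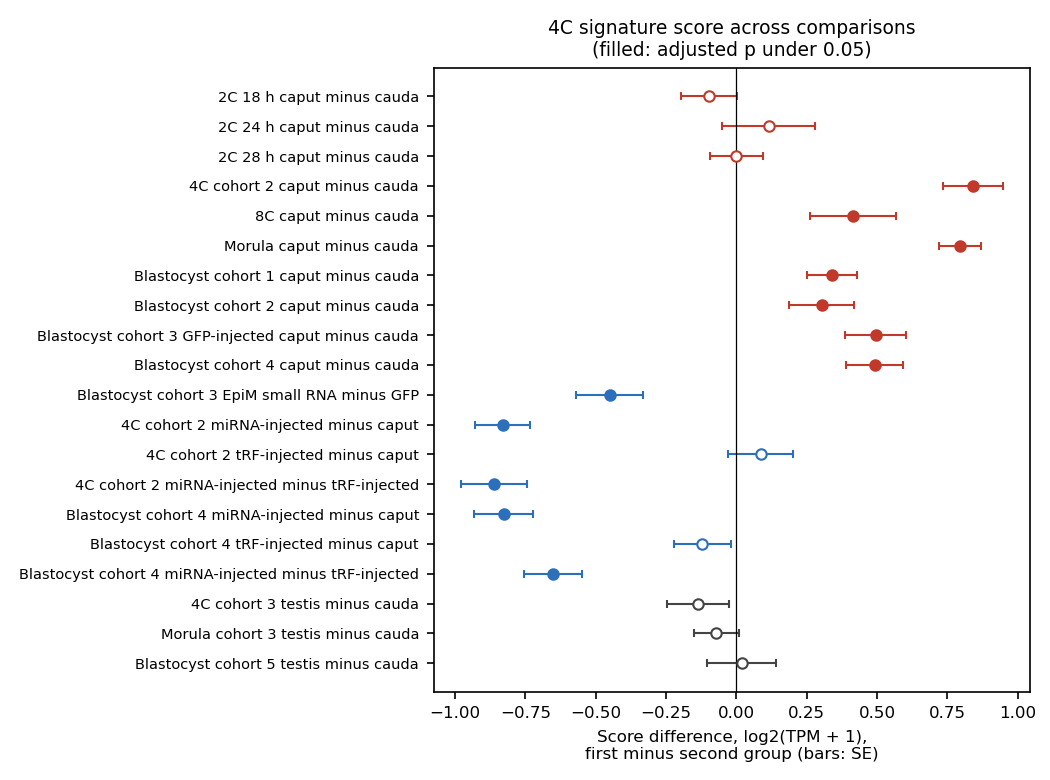
Differences of the 4C signature score on the log2(TPM + 1) scale between the groups of 20 comparisons, with bars for the SE and filled points for an adjusted permutation p under 0.05. Caput minus cauda lies above 0 from the 4-cell stage on (0.303 to 0.84), EpiM small RNA and miRNA lie below 0, and tRF and testis sperm lie within -0.137 and 0.086. Within a cohort, caput minus cauda shares its caput libraries with the injection comparisons, so a high score in those alone would give both signs. The comparisons of miRNA with tRF do not use these libraries.

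Testis sperm, which have not entered the epididymis, were compared with cauda sperm at the 4-cell, morula and blastocyst stages. At the 4-cell stage (34 and 33 embryos), 1 gene was higher and 1 lower of 11471, with 861 at an unadjusted p under 0.05: Isca2, for a protein of iron-sulfur cluster assembly, was at 79.0 ± 30.8 against 49.2 ± 15.3 TPM (SD, adjusted p = 0.0138), and Wdr5b fell by 1.20 ± 0.23 on the log2 scale (adjusted p = 0.0138), a gene outside the rule for named genes that was chosen after its values were seen. Both calls ended with the embryo number as a block and with a single mean per session and group (0 genes in limma, 817 and 858 at an unadjusted p under 0.05). At the blastocyst stage (28 and 29 embryos), 0 of 12062 genes passed in limma and 568 had an unadjusted p under 0.05. Ezr, for ezrin, had one of the 2 smallest p values there, at 85.9 ± 30.1 against 117.5 ± 27.0 TPM (adjusted p = 0.993). The 4C signature score differed by -0.137 ± 0.11, -0.071 ± 0.08 and 0.019 ± 0.122 at the 3 stages, with adjusted permutation p values of 0.42, 0.53 and 0.98. The testis-cauda difference minus the caput-cauda difference (4-cell cohort 2, morula, blastocyst cohort 4) was -0.977 ± 0.161 at the 4-cell stage, -0.864 ± 0.11 at the morula stage and -0.472 ± 0.158 at the blastocyst stage, with adjusted permutation p values of 3.3e-05, 3.3e-05 and 0.013. These contrasts set separate cohorts, sessions and cauda embryos against each other (mean cauda scores of -0.566 against -1.017, -1.124 against -1.385 and -1.188 against -1.557), so sperm source and cohort cannot be separated in them. The genes of the score can also differ between the cohorts, and how much this moves the contrasts was not tested.

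In morulae of testis sperm (34 and 34 embryos), 133 genes were higher and 53 lower of 11790, and 0 of the genes called higher with caput sperm in 4-cell cohort 1 were among the lower ones (0.504 by chance). Socs3, for a suppressor of cytokine signalling (chromosome 11, 117966079 to 117970336), was at 106.6 ± 56.7 against 53.9 ± 48.6 TPM (SD, 2.53-fold, adjusted p = 0.0105), and Elovl3, for a fatty acid elongase, at 25.5 ± 28.0 against 8.92 ± 12.9 TPM. Hspa8, for a constitutive heat shock protein, was at 9286 ± 1402 against 7369 ± 1537 TPM (1.28-fold), and Obox6, a homeobox gene of the maternal list, at 764.7 ± 328.0 against 486.5 ± 222.1 TPM. The trophectoderm genes Dppa1 and Id2 were lower, at 13.5 ± 14.1 against 36.9 ± 33.4 TPM and 3.58 ± 5.28 against 11.1 ± 11.4 TPM, as 2 of 27, with adjusted p = 0.634 with an estimated correlation for the list. The pluripotency genes Nr5a2 and Dppa4 were higher, as 2 of 23 (8 adjusted over the list alone), with a list adjusted p of 0.00562 at a preset correlation and adjusted p = 0.237 with an estimated correlation. Of 80 nuclear genes for oxidative phosphorylation, 15 had a higher value and 3 were called lower, among them Ndufb9, with a list adjusted p of 1.5e-10 at a preset correlation and adjusted p = 0.237 with an estimated correlation. A cauda morula held 4864 genes at 1 TPM or more and correlated with its group at 0.73; without it 559 genes passed, 288 higher and 271 lower. With the GC trend removed 161 were higher and 109 lower, and with the length trend removed 171 and 111. With the embryo number as a block 25 passed, with a pseudocount of 0.1 57, without the filter on low values 60, without the session term 109, and with a single mean per session and group 0 did in limma (1350 at an unadjusted p under 0.05).

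**Figure D3:**
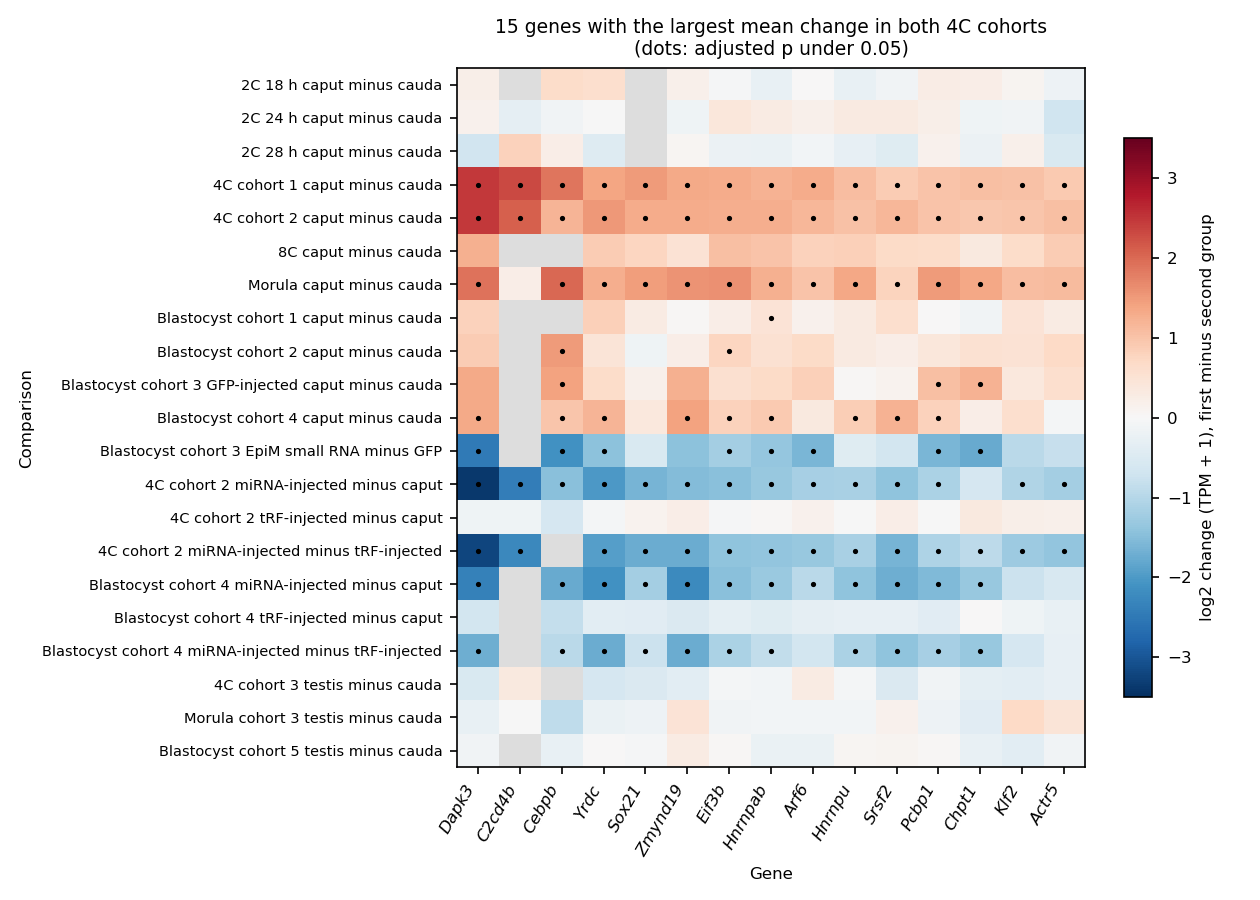
Log2 change (TPM + 1 scale) in 21 comparisons of the 15 genes with the largest mean change among those called in both 4-cell cohorts; colour gives the change, dots an adjusted p under 0.05 and grey a gene that was not tested. The changes between caput and cauda sperm at the 4-cell stage are positive by selection. In 4-cell cohort 2, miRNA and tRF are compared with the same caput libraries, so the selection favours negative values there. Dapk3 reaches -3.38 after miRNA injection in that cohort.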

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

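The tests of explanations, the tests of differences between stages and the limit of 5% for the counts over other splits of the samples were all written down after results were seen. The difference of the 4C signature score between caput and cauda sperm was itself compared between stages. From 2-cell embryos at 28 h to 4-cell cohort 2 it rose by 0.84 ± 0.143 (SE, adjusted permutation p = 3.3e-05). From 4-cell cohort 2 to 8-cell embryos it changed by -0.425 ± 0.184 (adjusted permutation p = 0.046), from 8-cell embryos to morulae by 0.378 ± 0.158 (0.046), and from morulae to blastocyst cohort 4 by -0.303 ± 0.126 (0.042). From 4-cell cohort 2 to morulae it changed by -0.046 ± 0.127 (0.72). In these contrasts the stages were studied in different sessions, so stage and session cannot be separated. The genes of the score were chosen at the 4-cell stage, which favours a larger difference there. They can also differ between stages, and how much either moves the differences was not tested. The 8-cell difference rests on 3 sessions with both groups, and 4 of the 8-cell libraries correlated with their group below 0.85. In the sole group of 4 to 10 embryos, the 8 cauda embryos at 24 h, no embryo lay far from the others in score, genes at 1 TPM or correlation: the gap was 0.436, 0.336 and 0.276 of the range, under the limit of Dixon's test.

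The pattern of genes higher with caput sperm in 4-cell cohort 1 was set against technical explanations. A trend between libraries with GC share at the 5-prime end is argued against as the whole cause, since 94.1% of the median change stayed after its removal (0.763 before and 0.718 after) and 104 of 114 genes were still called. A rise or fall with library number in a single direction cannot be told apart from sperm source at the 4-cell stage. The library number is the sample number in the description. In 4-cell cohort 1 only 16 of 64 libraries have such a number, and in 4 of 4 sessions of 4-cell cohort 2 the caput libraries carry the higher ones. Over all later stages and 4-cell cohort 2, the score was higher with caput sperm in 90.9% of the 11 sessions whose caput libraries carry the lower numbers, which are 3 of morulae and 8 of blastocysts, and in 89.5% of the 19 where they carry the higher ones. What stays open as well is an axis of variation that is present without caput sperm. In 4-cell embryos of testis and cauda sperm these genes had a mean pairwise correlation of 0.228 within group and session, where lists matched on level and GC had a median of 0.027 and at most 0.061. Embryos there were also ordered by the embryo number in the title, which can differ from the library number above. The score of an embryo correlated with that of the next embryo at 0.289 (permutation p = 0.0008, 0.0021 adjusted over 8 such tests). The rank correlation was 0.298, and without the 2 farthest pairs the correlation was 0.264. Over the 8 tests the correlation of neighbouring embryos was 0.109 to 0.449, and 6 had an adjusted p under 0.05. The other 2 were 4-cell cohort 2 (0.109, adjusted p = 0.057, and 0.354 without the 2 farthest pairs) and blastocyst cohort 4 (0.196, adjusted p = 0.057, and -0.054 without the 2 farthest pairs). A factor shared by embryos or libraries handled together may therefore move these genes, and the labels do not say what the numbers stand for. It could be technical, or a difference between clutches or males, and neither was tested. The within-session permutations take embryos as exchangeable, which this correlation speaks against. The sperm source is the biological explanation that the design gives, and it stays open too.

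The genes called in blastocyst cohort 1 were weighed in the same way. A trend with transcript length is argued against as the whole cause, since 84.5% of the median absolute change stayed after its removal and 199 of 259 genes were still called. Differences between sessions and the sperm source cannot be told apart for these genes. Over 5 fits, each without a session, 780 calls were made, in which a gene counts once per fit and of which 484 came from the fit without session day120. Of these calls 56.9% kept their sign in the session left out, and without those of session day120 it was 79.1%, so a single session keeps the test open. In 4-cell cohort 1, morulae and blastocyst cohort 4 the shares were 85.4%, 92.2% and 67.1%. This test replaced a comparison with a single mean per session and group (113.3% of the change kept), whose outcome is nearly fixed by its block for session. The condition on the session of lowest share was set after 56.9% had been seen.

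Each count of called genes was compared with the counts from 100 splits of the same embryos into groups of the same sizes within sessions, the real split included. A chance split of exchangeable embryos is argued against at 5% for 4-cell cohort 1 (130 genes, highest other split 2, as many in 1 split) and 4-cell cohort 2 (66, highest other 7, in 1). The same holds for blastocyst cohort 2 (34, highest other 3, in 1), cohort 3 GFP against cauda (53, highest other 1, in 1) and cohort 4 (222, highest other 37, in 1). It also holds for miRNA against tRF at the 4-cell stage (94, highest other 2, in 1) and in blastocysts (177, highest other 3, in 1), and for testis morulae (186, highest other 1, in 1). For testis 4-cell embryos (2, highest other 2, in 2) and at 18 h (1, highest other 1, in 4) the share is under 5% too, yet other splits gave as many genes, so little rests on it. These shares were not adjusted for the 21 comparisons. The splits take the embryos of a session as exchangeable. The correlation between embryos neighbouring in number speaks against that in the 6 comparisons above where it passed, among them morulae (0.332) and testis 4-cell embryos (0.289). That correlation was not computed for 4-cell cohort 1, blastocyst cohorts 1 to 3 or EpiM small RNA, among others. The splits also cannot tell sperm source from any other difference between the groups of a session. In morulae (99, in 3), blastocyst cohort 1 (259, in 3), EpiM small RNA (53, in 4), miRNA 4-cell embryos (147, in 2) and miRNA blastocysts (370, in 2) the share is under 5%, yet the highest other splits gave 576, 555, 1900, 174 and 459 genes. Splits that call several times the real count (576 in morulae and 1900 for EpiM small RNA) point to a structure of the samples, and what it is was not tested. For tRF 4-cell embryos 11 splits gave as many genes as the real split (1, highest other 7), so chance is not excluded. Where 0 genes were called in limma, 100 of 100 splits gave as many, with highest others of 5 at 24 h, 2 at 28 h, 2 in 8-cell embryos, 1 for tRF blastocysts and 0 for testis blastocysts, and 554, 1031, 541, 723 and 568 genes at an unadjusted p under 0.05.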

How the results depend on the processing

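The fits without low-correlation libraries, with the GC or length trend removed and with a session left out were chosen after the data were seen. The other alternatives were planned. No value that passed its test reversed its direction. None of the values of named genes changed direction in the alternative fits where they were tallied, and the fits with a session left out were not tallied. Of 329 values of named genes, 276 were still called with a pseudocount of 0.1, 259 without the filter, 235 without the session term, 264 with the GC trend and 275 with the length trend removed, and 32 with a single mean per session and group. With the embryo number as a block, 193 of 293 were still called. Counts of called genes stayed within 1.5 times in 19 of 21 comparisons with a pseudocount of 0.1, in 17 without the filter, in 15 each with the GC or length trend removed and in 14 of 20 without the session term. These are totals, and the parts higher and lower moved further in some. Where they moved, the cause was not tested unless stated.

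A single mean per session and group leaves fewer samples. It gave 20 genes in 4-cell cohort 1, 39 in morulae, 7 for miRNA against tRF at the 4-cell stage and 1 in 8-cell embryos. It gave 0 in limma at 18 h, in 4-cell cohort 2, in blastocyst cohorts 1 to 4, for EpiM small RNA, for miRNA against caput in 4-cell embryos and blastocysts, for tRF at the 4-cell stage, for miRNA against tRF in blastocysts, and for testis 4-cell embryos and morulae (in this order 783, 737, 1080, 903, 1515, 948, 347, 560, 775, 624, 421, 858 and 1350 genes at an unadjusted p under 0.05). The embryo number as a block gave 0 in limma at 18 h, in blastocyst cohort 1, for tRF and for testis 4-cell embryos (488, 1556, 952 and 817 genes at an unadjusted p under 0.05), 1 in 8-cell embryos, 306 in blastocyst cohort 2, 89 for miRNA against tRF in blastocysts and 25 in testis morulae. Embryos of the same number were not taken as pairs, since the lowest correlation of such embryos was below 0.1 in all 19 comparisons (-0.313 to -0.087). The lowest of many noisy values tends to be low, so this rule cannot decide whether they were pairs. The median correlation of such embryos was highest in blastocyst cohort 4, at 0.181, 0.158 and 0.095 for miRNA against caput, tRF against caput and miRNA against tRF, where other pairs had medians of -0.008, -0.009 and 0.001. For miRNA and tRF against caput there, 17 and 15 of 29 pairs exceeded 0.1.

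Without the session term the counts were 0 at 18 h (limma, 684 at an unadjusted p under 0.05), 17 in blastocyst cohort 1, 79 in cohort 2, 22 in cohort 3, 87 for miRNA against tRF in blastocysts and 109 in testis morulae. Without the filter they were 140 in blastocyst cohort 1, 32 in cohort 3, 33 for EpiM small RNA and 60 in testis morulae. With a pseudocount of 0.1 they were 25 for EpiM small RNA and 57 in testis morulae. With the GC trend removed they were 416, 2, 82 and 97 in blastocyst cohorts 1 to 4, 2 for tRF at the 4-cell stage and 226 for miRNA against caput in blastocysts. With the length trend removed they were 2, 89 and 129 in blastocyst cohorts 2, 3 and 4, 82 for EpiM small RNA, 10 for tRF at the 4-cell stage and 282 in testis morulae. Testis morulae without the cauda library at a correlation of 0.73 gave 559 genes, against 186 with it. The other 3 comparisons with such libraries stayed within 1.5 times.

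The 4C signature score, where it passed, kept its direction, and it kept its side of the threshold except with 300 genes per direction in 8-cell embryos (0.199, adjusted permutation p = 0.55), blastocyst cohort 2 (0.066, 0.75), cohort 4 (0.206, 0.051) and EpiM small RNA (-0.089, 0.75), and with 30 in blastocyst cohort 2 (0.359, 0.066). Over its alternatives the adjusted p ranged from 0.00062 to 0.55 in 8-cell embryos, from 0.00056 to 0.75 in blastocyst cohort 2, from 0.00012 to 0.051 in cohort 4 and from 0.00062 to 0.75 for EpiM small RNA. The Blastocyst signature score in cohort 2 passed without the session term (0.321, 0.0076; over its alternatives 0.0076 to 0.37). Score differences that did not pass in any setting changed sign in 5 comparisons, and the cause was not tested. The 4C score did so at 28 h (0.0, then -0.098 with 30 genes and -0.033 without the session term) and for tRF blastocysts (-0.121, then 0.044 with 300). The Blastocyst score did so in cohort 4 (0.026, then -0.018 with 30), for EpiM small RNA (-0.003, then 0.03 with 300, 0.003 with a pseudocount of 0.1 and 0.004 without the session term) and in testis blastocysts (-0.002, then 0.001 with 300). At an adjusted p under 0.1 the blastocyst cohorts shared 7 genes (cohorts 1 and 2), 5 (1 and 3), 43 (1 and 4), 3 (2 and 3), 14 (2 and 4) and 13 (3 and 4). Of 576 gene list tests, 102 passed at the preset correlation and 3 with the estimated one, which allows for members that vary together. Depth is unknown, so what it limits could not be computed.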

Other observations

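Some gene lists had median changes of both signs over the stages and cohorts. Most oxidative phosphorylation genes had a higher value with caput sperm at 18 h (68 of 79 higher, median 0.21), a lower value at 28 h (21 of 79 higher, median -0.1), a higher value in 8-cell embryos (68 of 80, median 0.15) and a lower value in blastocyst cohort 1 (9 of 79, median -0.14), with adjusted p of 1.59e-14, 5.21e-06, 0.000374 and 1.66e-11 at a preset correlation and 0.149, 0.952, 0.944 and 0.617 with an estimated correlation. Targets of p53 were mostly higher with caput sperm in blastocyst cohorts 1 and 2 (19 of 22 in each, medians 0.29 and 0.38) and mostly lower in cohort 4 (6 of 22 higher, median -0.16) and in 8-cell embryos (5 of 22 higher, median -0.44). None of these lists passed with an estimated correlation. The differences between stages and between cohorts were not tested. Over all tested genes, the moderated t correlated with transcript length at -0.27 at 18 h and -0.2 in 8-cell embryos. At 28 h this correlation was 0.25, and in blastocyst cohort 1 it was 0.35. The oxidative phosphorylation list has the opposite sign in each, and whether a trend with length gives its signs was not tested.

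Primitive endoderm genes were mostly higher with caput than with cauda sperm in blastocyst cohort 4 (20 of 22, median 0.44), and lower in the same cohort after miRNA (2 of 22 higher, median -0.44) and after tRF (1 of 21 higher, median -0.58) than in the caput embryos. The 3 comparisons share the caput libraries, so a high level in those libraries alone gives all 3. In blastocyst cohort 3 the list went the other way (3 of 17 higher, median -0.2), and with testis sperm 1 of 22 was higher (median -0.28).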
